A study of Mus musculus with 10 samples.

How the data were processed

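RNA was taken from the submandibular glands of C57BL/6J mice aged 8 weeks, whose sex is given as female. In 1 group the duct of the right gland had been tied off, and in the other the skin had been opened and the gland freed without tying the duct. Glands were taken at day 7, with 5 libraries in each group, 10 in all, and the design text gives 5 mice per group. Replicate numbers come from the sample titles. Per the labels, RNA was purified on silica columns and libraries were made with a SMARTer messenger RNA kit.

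The values used are 1 table of FPKM (fragments per kilobase of gene model, relative to library size) for 55291 genes, made and deposited by the authors with 1 column per library. The genome build is GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program and the annotation are not given in the sources used here. The FPKM sums differ between libraries, from 337121 to 604875, so the authors applied no scaling that would equalise them. Of the gene symbols, 53292 (96.4%) are in the GENCODE M21 annotation, and 28537 genes were at 0 in every library. Every column of the table belonged to a sample (0 columns were left over), and 0 pairs of libraries held identical values.

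Depth was worked out from the values. When the FPKM of a gene is multiplied by its merged exon length in GENCODE M21, low values (below 200 reads) fall on whole multiples of 1 step per library. With a tolerance of 0.01 of a read, 98.1% to 98.3% of them were whole. The step corresponds to between 12105738 and 17305592 reads assigned to genes per library. Among the lowest of the whole values, between 67.6% and 75.6% were even multiples, and whether 1 unit is a read or a read pair is not known. If both mates of a pair were counted, the libraries held fewer fragments than these reads. In a gene of 1 kilobase, 3 reads amount to between 0.173 and 0.248 FPKM, and values near or below this level rest on very few reads.

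FPKM are not counts, so genes were compared on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3. A linear model with the 2 groups and no covariate was fitted, followed by empirical Bayes moderation with a mean-variance trend. P-values are two-sided and adjusted by the Benjamini-Hochberg method. Genes with at least 1 FPKM in at least 5 of the 10 libraries were tested, which left 11856. A gene below 1 FPKM in every sham library enters only if all 5 ligated values reach 1. This favours rises in lists with many such genes. A gene was called changed at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. The pseudocount understates the change of genes with low values. No batch is given in the labels. P-values measure the spread between mice.

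Before the data were examined, 38 gene lists were fixed for the cell types of the gland, tissues that can lie next to it, and processes linked to obstruction and inflammation. Lists with at least 4 tested members (37 of them) were tested against all other genes with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares the moderated t-statistics of a list with those of other genes. A list it calls lower therefore need not hold genes that fell, and genes with a large spread get small t-statistics. Camera was repeated with the correlation estimated for each list. Limma's fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes. The share of the summed FPKM taken by each list was compared with an exact permutation test of the difference in means, two-sided, with Benjamini-Hochberg adjustment over the 38 lists. With 5 libraries against 5 the smallest p this test can give is 0.00794. Principal components and Pearson correlations between libraries were described and not tested.

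The named genes follow a rule fixed at the same time. It takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 FPKM, no overlap between the groups and a symbol that is not a predicted gene model. It also takes up to 4 called members of each list, those with the largest change, or the member with the highest mean where none was called. The rule gave 126 genes, not all of which are printed. A few genes are not reported here. Genes named outside the rule were chosen after their values were seen. Positions are those of GENCODE M21 on GRCm38.

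The fit was tested on simulated data with the means and spread of these libraries and 200 changed genes. At a log2 change of 1.5, 88% of the changed genes were recovered, and at 3, 98%. Of 11636 unchanged genes, 3 were called. Of 20 unchanged lists, 0 were called. Each gene was drawn independently of the others and the unchanged lists were random genes. The simulation therefore held no correlation between genes and no outlying library, and false calls of lists under such correlation were not tested by it.

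Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, rescaling of each library to the same sum, quantile normalization, the replicate number as a block, robust moderation, no fold threshold, each library left out in turn, and shares without the 20 highest genes. After the data had been seen, 4 more were added. They were the lymph node and parotid marker levels as covariates, fits without the 4 libraries with lymph node transcripts or without the 4 with parotid transcripts (each with at least 1 FPKM in at least 3 libraries), and limma's voom on the recovered whole reads. Of the ligated group, the fit without lymph node libraries kept only ligated 4 and 5. The fit without parotid libraries kept only ligated 1 and 4. Calls can be lost in these fits through the smaller number of libraries alone. Scripts also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

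Values of some genes cannot be assigned with certainty. The Klk1b, Dcpp and Scgb families, the amylase genes and the immunoglobulin genes have near-identical copies, and how the authors' counting divided shared reads is not known. Muc19 and Smgc overlap. Whether strand was used is not given in the sources used here, so reads of a gene and an antisense partner cannot be separated where their exons overlap, which for Xist and Tsix is 11.03% of the Xist exon bases.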

Results

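The series compared submandibular glands of mice 7 days after the duct had been tied with glands after a sham operation. Tying the duct blocks the outflow of saliva and is used as a model of obstructive inflammation of the gland. RNA sequencing gave 10 libraries, 5 ligated and 5 sham, and the question addressed was how gene expression in the gland differs after obstruction. The libraries held between 12105738 (sham 4) and 17305592 (sham 3) assigned reads, as worked out from the values, and 14333039 in ligated 4, the next highest after sham 3. At least 1 FPKM was listed for 9860 to 12060 genes in the sham libraries and 12307 to 13162 in the ligated libraries.

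The sham glands were dominated by a few secretory transcripts. The 20 highest genes of each library took 54.1% to 76.3% of the summed FPKM in sham glands and 24.9% to 47.5% in ligated glands. Mucl2, a mucin-like gene, was the highest gene in all 5 sham libraries, with 20.5% to 36.7% of the sum, and in ligated 1 (9.74%) and ligated 4 (4.59%). In ligated 2, 3 and 5 the highest gene was Bpifa2, a salivary protein made in quantity by the parotid gland, with 4.83% to 9.35%. The mice are labelled female, yet transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 10 libraries, with a lowest value of 0.770 FPKM. Xist, which is transcribed from the inactive X chromosome, reached at most 0.0267 FPKM.

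The first principal component held 61.6% of the variance and the second 19.98%. On the first, the lowest ligated library lay above the highest sham library by 9.26% of the range. Sham 1 narrowed that gap, which was 56.1% without it, and after median-ratio scaling or quantile normalization the groups overlapped (gaps of -15.5% and -16.8%). Leaving out ligated 5 reduced the gap to 1.57% and leaving out ligated 4 to 1.80%. Sham 1 correlated most closely with ligated 1 (r = 0.931 across genes), whereas the other sham libraries matched one another best.

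**Figure D1:**
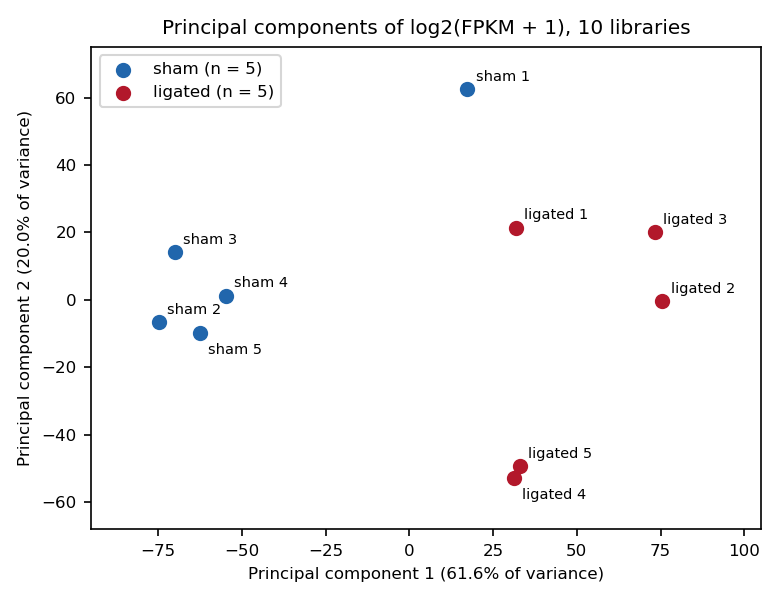
Principal components of log2(FPKM + 1) for the 5 sham (blue) and 5 ligated (red) libraries, each point a library, with the share of variance on each axis in percent. Sham 2 to 5 lie to the left, and sham 1 lies next to the ligated libraries, 9.26% of the range below the lowest of them.

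After duct ligation 8 of 16 acinar genes were lower and 0 higher. Of matrix genes 41 of 42 were higher, of macrophage genes 20 of 24, of adipocyte genes 9 of 9 and of skeletal muscle genes 9 of 9, though with an estimated correlation camera did not pass for these lists (adjusted p = 0.467, 0.409, 0.409 and 0.513). Mucl2 went from 145906 ± 49701 to 15168 ± 17052 FPKM (mean ± SD, n = 5 per group), and Muc19, a gel-forming salivary mucin, from 109 ± 48.2 to 6.44 ± 10.7 FPKM. Spdef, a transcription factor of mucous secretory cells, went from 59.8 ± 28.1 to 9.42 ± 3.99 FPKM. Timp1, an inhibitor of matrix metalloproteinases, went from 5.92 ± 4.81 to 233 ± 130.4 FPKM. Clu, which encodes the chaperone clusterin, went from 37.3 ± 47.7 to 853 ± 513 FPKM.

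On the log2(FPKM + 1) scale, used for all fold changes below and given with the SE, Timp1 rose by 4.97 ± 0.60 (limma, Benjamini-Hochberg adjusted p = 0.000212) and Clu by 4.72 ± 0.73 (adjusted p = 0.00069). Muc19 fell by 4.70 ± 0.73 (adjusted p = 0.000681) and Spdef fell by 2.54 ± 0.33 (adjusted p = 0.000314). Mucl2 fell by 3.86 ± 0.77 (adjusted p = 0.00259), a call that was lost with no filter (adjusted p = 0.36) and with quantile normalization (adjusted p = 0.147; range over the alternatives 8.90e-05 to 0.36). On GRCm38, Timp1 (ENSMUSG00000001131.11) lies on chromosome X at 20870166 to 20874735, Clu (ENSMUSG00000022037.15) on chromosome 14 at 65968483 to 65981547, and Spdef (ENSMUSG00000024215.14) on chromosome 17 at 27714352 to 27728955. Muc19 (ENSMUSG00000044021.14) lies on chromosome 15 at 91838326 to 91934555, where it overlaps Smgc, and Mucl2 (ENSMUSG00000036925.8) on chromosome 15 at 103895855 to 103899312. The values are sums over the whole gene model of each.

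The other genes among the 10 largest rises were Cfd (6.48), Car3 (6.26), Acta1 (5.45), Thbs4 (5.23), Adipoq (5.05), Cidec (5.01), Atp2a1 (4.61) and the imprinted transcript H19 (4.61). Cfd, Adipoq and Cidec are known from adipocytes, Acta1 and Atp2a1 from skeletal muscle. The other genes among the 10 largest falls were A2ml1 (-5.72), a protease inhibitor, the demilune protein gene Dcpp2 (-4.77), the secretoglobins Scgb2b26 (-3.87), Scgb1b27 (-3.24) and Scgb2b27 (-3.07), Lman1l (-3.31) and Cgref1 (-2.63). Dcpp2 was at 0 in ligated 4, and its call (adjusted p = 0.0312) was lost without sham 2 (0.0545), sham 4 (0.0613) or sham 5 (0.0546), with a range over the alternatives of 0.00401 to 0.0814. Without ligated 4 it fell by 2.87. Dcpp and secretoglobin genes have near-identical copies, so the division of reads among them is uncertain. The copies Dcpp1 (-2.49 ± 2.02, limma adjusted p = 0.294) and Dcpp3 (-4.31 ± 1.79, adjusted p = 0.056) were not called. Dcpp1 stood at 2306, 3427 and 4748 FPKM in ligated 2, 3 and 5, and at 95.6 and 0 FPKM in ligated 1 and 4. In sham glands it stood at 539 to 4716 FPKM.

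**Figure D2:**
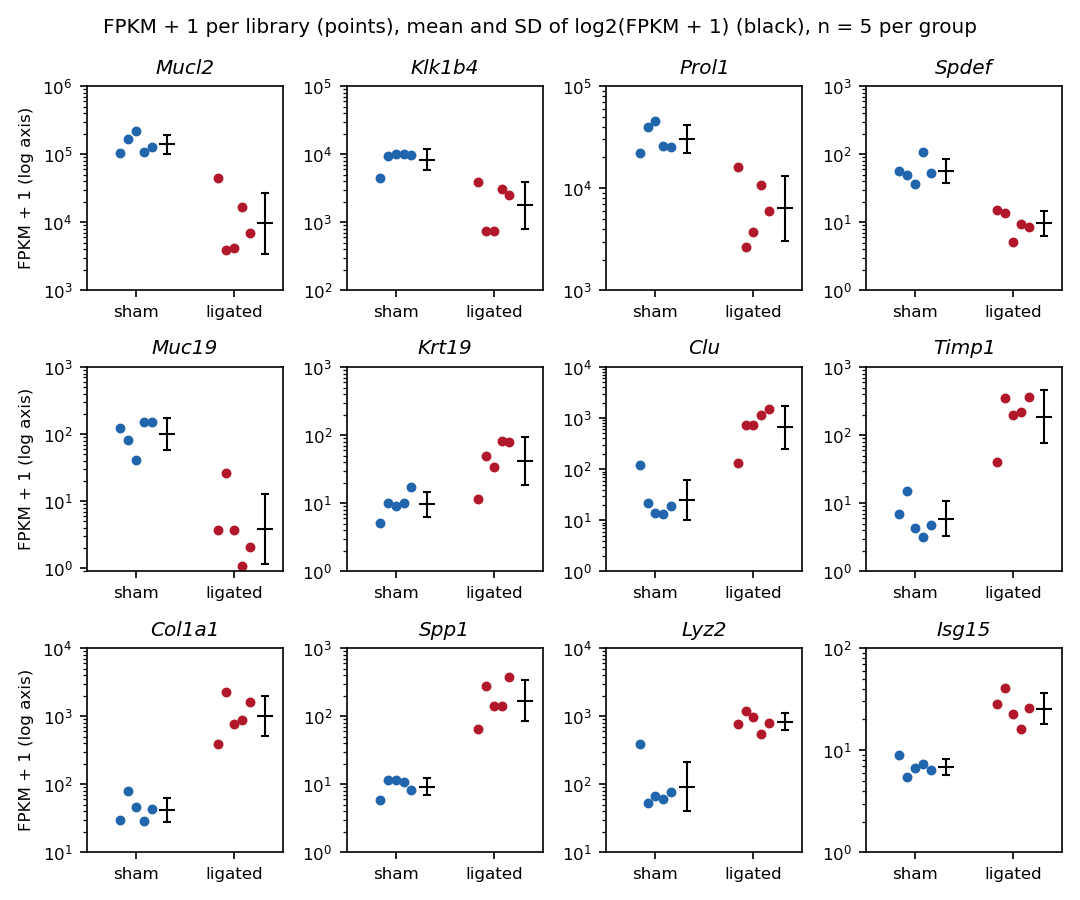
FPKM + 1 on a log axis for 12 named genes, with 1 point per library (blue sham, red ligated) and, in black, the mean and SD of log2(FPKM + 1), n = 5 per group. Mucl2, Spdef and Muc19 are lower in all 5 ligated libraries than in every sham library, and Timp1, Clu, Col1a1, Spp1, Lyz2 and Isg15 are higher.

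Of 11856 genes tested with limma, 2031 were higher and 138 lower in ligated glands, so that 93.6% of the calls were rises. At an adjusted p under 0.05 with no fold threshold, 6732 were higher and 397 lower. The groups did not overlap in 3710 genes (31.3%), where chance gives 0.794%. The median log2 fold change of all tested genes was 0.53. Median-ratio scaling brought this median to -0.01 and the calls to 811 higher and 498 lower (62.0% higher), and quantile normalization gave 689 higher and 509 lower (57.5% higher). With each library rescaled to the same sum, 6675 were higher and 78 lower (98.8% higher). In no alternative was a gene called in the opposite direction (0 genes in each). Medians of gene lists are therefore given relative to the median of all genes. Camera with the preset correlation called 15 of 37 lists higher and 10 lower, but with an estimated correlation only the acinar list kept its call, and 0 lists were higher. Lower here means relative to other genes. Among the lists called lower, the median log2 fold change was above 0 for fluid and ion secretion (0.13) and myoepithelial genes (0.15). The same held for oxidative phosphorylation (0.26), tight junction (0.31) and parotid and sublingual products (2.64).

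Acinar cells make the saliva proteins, mucins and fluid of the gland. Of 16 measured acinar genes, 8 were lower and 0 higher (0 higher and 9 lower when adjusted over the list alone), with a median 2.40 below that of all genes. Besides Muc19, Dcpp2 and Spdef, Prol1, a proline-rich mucin gene, fell by 2.26 ± 0.57, from 31632 ± 10153 to 7851 ± 5605 FPKM, a call that was lost with no filter (adjusted p = 0.271), quantile normalization (0.108) and the replicate block (0.0555). Muc19, Dcpp2 and A2ml1 followed Smgc, a gene listed here with sublingual gland products that overlaps Muc19, over the 5 libraries of each group (r of log2(FPKM + 1) of 0.98, 0.96 and 0.99 in sham and 0.95, 0.65 and 0.92 in ligated glands). In sham glands Lman1l (0.98), Cgref1 (0.96) and Spdef (0.84) followed it too, whereas Prol1 and Mucl2 ran against it (-0.89 and -0.94). Smgc was at 9.83 ± 6.35 FPKM in sham and 1.10 ± 1.47 FPKM in ligated glands, and at 0 in ligated 4. Camera placed the list lower (adjusted p = 2.69e-24), also with an estimated correlation (adjusted p = 0.0134). Its share of the summed FPKM went from 12.0% ± 1.77 to 4.49% ± 1.23 (exact permutation test, two-sided, p = 0.00794, adjusted p = 0.0126), and every ligated library lay below every sham library.

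The granular convoluted tubule, a duct segment that stores kallikreins and growth factors, is known to differ between the sexes in mice. Of its 19 listed products, 14 were lower and 0 higher (0 higher and 14 lower when adjusted over the list alone), with a median 2.43 below that of all genes. The kallikrein-related genes Klk1b3 (-2.56 ± 0.68), Klk1b1 (-2.25 ± 0.57) and Klk1b4 (-2.24 ± 0.54) fell, Klk1b4 from 8706 ± 2428 to 2206 ± 1419 FPKM. The call of Klk1b4 was lost with quantile normalization (adjusted p = 0.0636). Klk1 did not pass the test (0.91 ± 0.42, adjusted p = 0.0802), and reads of these genes can be shared. Camera gave an adjusted p of 4.77e-22, adjusted p = 0.374 with an estimated correlation, and 0.0532 with quantile normalization. The count of lower genes was 7 without sham 2, 3 or 5 or without ligated 2 or 3 (with 1 gene higher without ligated 3), 7 with the replicate block, 4 with no filter and 3 with quantile normalization. It was also 3 without the 4 libraries with parotid transcripts (sham 1 and ligated 2, 3 and 5). That fit kept only ligated 1 and 4 of the ligated group, so fewer libraries alone could lose calls. The share of the summed FPKM was 21.97% ± 4.45 in sham and 14.2% ± 9.15 in ligated glands and did not pass the exact test (two-sided, p = 0.135).

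Striated ducts and ionocytes modify the saliva by moving ions. Of 12 measured genes, 2 were lower, the transcription factor Tfcp2l1 (-1.37 ± 0.49) and the claudin Cldn8 (-1.07 ± 0.43), and 0 when adjusted over the list alone. Neither was called without sham 2, 3, 4 or 5 or ligated 2, 3 or 4, and without ligated 1 the count was 4. Without the 4 libraries with parotid transcripts the changes were -0.73 (adjusted p = 0.176) and -0.47 (adjusted p = 0.292), and 0 genes of the list were lower. Relative to all genes the list median was -0.86 (camera adjusted p = 3.64e-08; adjusted p = 0.374 with an estimated correlation). Among 25 genes of fluid and ion secretion, Atp1b3 (1.18 ± 0.23), a sodium pump subunit, and the bicarbonate transporter Slc4a4 (1.11 ± 0.24) were higher, and the sodium channel subunit Scnn1g (-1.02 ± 0.39) was lower. Adjusted over the list alone, 2 were higher and 0 lower. After median-ratio scaling 0 were higher and 4 lower. Without ligated 4 the call of Slc4a4 was lost (0.88), and without sham 2 to 5, ligated 2 or ligated 3 that of Scnn1g (adjusted p 0.0677 to 0.0906). Scnn1g was at -0.39 (adjusted p = 0.179) without the 4 libraries with parotid transcripts. The list's median was -0.40 relative to all genes (camera adjusted p = 0.000478; adjusted p = 0.513 with an estimated correlation), a camera call lost with no filter (0.0705), with the covariates (0.0821) and without the 4 libraries with lymph node transcripts (0.15).

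Genes of the secretory pathway and the unfolded protein response serve protein folding in the endoplasmic reticulum. By limma, 0 of 28 were higher and 0 lower, also when adjusted over the list alone and with voom on recovered reads. At an unadjusted p under 0.05, 1 was higher and 5 lower. In other settings 7 were lower after median-ratio scaling and 2 without ligated 1. Hspa5, the main chaperone of that compartment, stood at 496 ± 109 FPKM in sham and 458 ± 126 FPKM in ligated glands (-0.13 ± 0.24, adjusted p = 0.635), and 0.43 with libraries rescaled to the same sum. The median of the list was -0.54 relative to all genes (camera adjusted p = 2.2e-10; adjusted p = 0.374 with an estimated correlation). Of 17 tight junction genes, 1 was higher and 1 lower, the claudin Cldn10 (-1.27 ± 0.28), also when adjusted over the list alone. Without ligated 4, 0 were higher, and after median-ratio scaling 0 were higher and 2 lower. The median of its members was -0.21 relative to all genes. Its camera call (adjusted p = 0.0309; adjusted p = 0.699 with an estimated correlation) was lost without sham 4 (0.0562) and without ligated 1 (0.146), 2 (0.0953) or 3 (0.106). It was also lost without the 4 libraries with lymph node transcripts (0.998), with no filter (0.813), with the lymph node and parotid covariates (0.797), with quantile normalization (0.12), with the replicate block (0.115), with a filter at 5 FPKM (0.0629) and after median-ratio scaling (0.0579).

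Keratins and progenitor markers of ducts and basal cells were higher in 7 of 20 measured genes and lower in 0, also when adjusted over the list alone, but after median-ratio scaling 0 were higher and 3 lower. Krt19 (2.12 ± 0.51) and Krt8 (1.54 ± 0.38), keratins of simple and ductal epithelium, rose as deposited, Krt8 from 217 ± 30.9 to 721 ± 377 FPKM, and their calls were lost after median-ratio scaling (1.48 and 0.86) and without the 4 libraries with parotid transcripts (1.45 and 1.22). In that last fit, which kept only ligated 1 and 4 of the ligated group, 3 genes were called higher, and without the 4 with lymph node transcripts 11. Without ligated 2, 1 gene was lower. The list median lay 0.29 above that of all genes, while camera pointed lower without passing (adjusted p = 0.639). Genes of epithelial injury and the acute phase were higher in 14 of 15 measured (26 listed) and lower in 0, also when adjusted over the list alone and after median-ratio scaling. The filter favours members that are high in all ligated libraries. Besides Clu, haptoglobin Hp (4.29 ± 0.44) went from 9.65 ± 1.33 to 254 ± 164 FPKM, lactoferrin Ltf (3.33 ± 0.29) from 1.30 ± 0.763 to 22.5 ± 7.76 FPKM, and Orm1 rose by 2.39 ± 0.33. The list median was 1.66 above all genes (camera adjusted p = 4.39e-05; adjusted p = 0.485 with an estimated correlation).

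Extracellular matrix genes, which encode collagens, other matrix proteins and their modifiers, rose nearly as a whole. Of 42 measured, 41 were higher and 0 lower, also when adjusted over the list alone, and 38 were higher after median-ratio scaling. Col1a1, the main chain of type I collagen, went from 44.6 ± 20.2 to 1180.5 ± 739.8 FPKM (4.55 ± 0.45, adjusted p = 0.000102; ENSMUSG00000001506.10, chromosome 11 at 94936224 to 94953042). Tnc, which encodes the wound matrix protein tenascin C (4.53 ± 0.69), rose as well. The 42 genes had a median 2.48 above all genes (camera adjusted p = 5.77e-14; adjusted p = 0.467 with an estimated correlation). The list took 0.106% ± 0.00736 of the summed FPKM in sham glands and 1.84% ± 1.05 in ligated glands (exact permutation test, two-sided, adjusted p = 0.0126). Of 18 fibroblast and mesenchymal genes 14 were higher and 0 lower, also when adjusted over the list alone, and 11 after median-ratio scaling. Cthrc1 (3.38 ± 0.47), Fbln2 (3.24 ± 0.40), Dpt (2.96 ± 0.33) and the intermediate filament gene Vim (2.96 ± 0.39) led it. The list's median was 1.502 above all genes (camera adjusted p = 9.75e-05; adjusted p = 0.467 with an estimated correlation).

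Macrophage and monocyte genes were higher in 20 of 24 and lower in 0, also when adjusted over the list alone, and 18 were higher after median-ratio scaling. Gpnmb (4.21 ± 0.23), a marker of lipid-laden and repair macrophages, went from 0.304 ± 0.177 to 24.4 ± 10.6 FPKM, and Spp1 (4.19 ± 0.42), which encodes osteopontin, from 8.56 ± 2.50 to 200.4 ± 126.6 FPKM. The lysozyme gene Lyz2 (3.17 ± 0.49) and the cathepsin gene Ctss (2.80 ± 0.34) rose too. Lyz2 stood at 394 FPKM in sham 1 and the median of the sham group was 66.5 FPKM. The median of the list was 1.43 above all genes (camera adjusted p = 1.85e-07; adjusted p = 0.409 with an estimated correlation). All 6 measured neutrophil genes, of 15 listed, were higher, also when adjusted over the list alone, led by the calprotectin genes S100a9 (3.59 ± 0.89) and S100a8 (3.26 ± 0.68), with Retnlg (2.23 ± 0.26) and Csf3r (1.96 ± 0.22). The filter left out the other members and favours genes that are high in all ligated libraries, so this count is partly set by it. The mean log2(FPKM + 1) of the list was highest in libraries with lymph node transcripts, at 2.40, 2.13 and 2.38 in ligated 1 to 3 and 1.38 in sham 1, against 1.09 and 0.94 in ligated 4 and 5 and at most 0.25 in sham 2 to 5. S100a9 stood at 21.2 FPKM in sham 1 and at 12.3 and 6.94 FPKM in ligated 4 and 5. Their median was 1.57 above all genes (camera adjusted p = 0.0228; adjusted p = 0.513 with an estimated correlation), and the camera call was lost without ligated 1 (0.146), 2 (0.0511) or 3 (0.07). All 4 measured mast cell genes, of 9 listed, were higher, also when adjusted over the list alone, with the proteases Cma1 (2.08 ± 0.30) and Mcpt4 (1.90 ± 0.38) first and a median 1.18 above all genes. The same limit of the filter holds for this count. Camera did not pass for this list (adjusted p = 0.091) and passed without ligated 5 (0.0198) and after median-ratio scaling (0.00785).

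Lymphocyte transcripts were unevenly spread over the libraries of both groups. The mean log2(FPKM + 1) of the lymph node list, which holds genes of follicles and high endothelial vessels, was 4.10 in sham 1 and 3.51, 3.58 and 3.92 in ligated 1 to 3, and at most 0.79 in the other 6 libraries. Of the 2 lymph node genes that passed the filter, limma called 0 higher and 0 lower, also when adjusted over the list alone, with voom and at an unadjusted p under 0.05, and without sham 1 both were higher. The chemokine gene Ccl21a, the more abundant of them, stood at 53.0 ± 101 FPKM in sham and 83.1 ± 64.5 FPKM in ligated glands (1.77 ± 1.04, adjusted p = 0.151). T and NK cell genes were higher in 6 of 16, and in 4 when adjusted over the list alone. Without sham 1 they were higher in 12 and without ligated 4 in 11. Without sham 2, 3 or 5 or ligated 1 or 3 the count was 3, without sham 4 it was 2, and after median-ratio scaling it was 0. Il7r (1.98 ± 0.58), the receptor of interleukin 7, was among them and stood at 6.88 FPKM in sham 1. Trbc2, a T cell receptor chain, was also called (3.24 ± 1.06), and not without sham 2 (adjusted p = 0.0572), 3 (0.0599) or 4 (0.0503). The median of its members was 1.20 above all genes and camera did not pass (adjusted p = 0.754), but did after median-ratio scaling (0.00813) and quantile normalization (0.00614). Of 7 B and plasma cell genes only Sdc1 was higher (2.24 ± 0.31), also when adjusted over the list alone, and 3 were higher without sham 1. Sdc1 encodes a surface proteoglycan of plasma cells that epithelial cells also carry. Their median was 1.68 above all genes, while camera pointed lower without passing (adjusted p = 0.714).

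Antigen presentation and dendritic cell genes were higher in 11 of 18 and lower in 0 (12 higher when adjusted over the list alone), and 5 were higher after median-ratio scaling. The integrin gene Itgax (2.07 ± 0.23) and the class II genes H2-Ab1 (1.93 ± 0.47), Cd74 (1.88 ± 0.50) and H2-Eb1 (1.83 ± 0.41) were among them. H2-Ab1 stood at 212 FPKM in sham 1, the library with the highest lymph node level, and at 197 ± 45.2 FPKM in ligated glands. The list median was 0.99 above all genes. Its camera call (adjusted p = 0.0175; adjusted p = 0.699 with an estimated correlation) was lost without sham 4 (0.0562), without ligated 1 (0.0593) and with libraries rescaled to the same sum (0.0505).

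**Figure D3:**
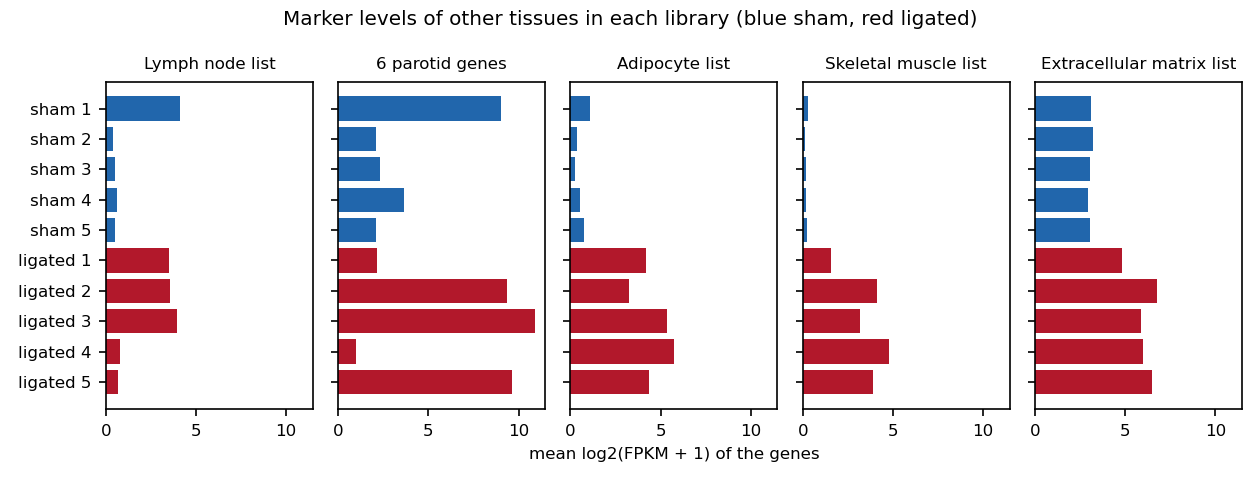
Mean log2(FPKM + 1) of the lymph node list, 6 parotid genes, and the adipocyte, skeletal muscle and extracellular matrix lists in each library, as bars (blue sham, red ligated). Lymph node levels are above 3.5 in sham 1 and ligated 1 to 3, parotid levels are above 9 in sham 1 and ligated 2, 3 and 5, and the extracellular matrix bars of all 5 ligated libraries are above those of all sham libraries.

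Chemokine and cytokine genes were higher in 24 of 28 and lower in 0, also when adjusted over the list alone, and 13 were higher after median-ratio scaling. They included the alarmin Il33 (3.38 ± 0.55) and the monocyte chemokines Ccl7 (2.57 ± 0.52), Ccl8 (2.50 ± 0.35) and Ccl2 (2.50 ± 0.40), the last from 2.96 ± 1.13 to 24.0 ± 13.0 FPKM. The list's median was 1.12 above all genes (camera adjusted p = 3.22e-05; adjusted p = 0.374 with an estimated correlation). Interferon response genes were higher in 19 of 25 and lower in 0, also when adjusted over the list alone, and 5 after median-ratio scaling. Isg15 (1.89 ± 0.23) went from 5.97 ± 1.28 to 25.7 ± 9.21 FPKM, with Gbp2 (1.84 ± 0.27) and Ifit3 (1.67 ± 0.29) next. The median of the list was 0.87 above all genes (camera adjusted p = 0.000123; adjusted p = 0.513 with an estimated correlation). Of 12 complement genes 9 were higher and 0 lower, also when adjusted over the list alone, and 6 after median-ratio scaling. The anaphylatoxin receptors C3ar1 (2.42 ± 0.29) and C5ar1 (2.21 ± 0.33) and the inhibitor Serping1 (2.13 ± 0.28) rose. The median of its members was 1.503 above all genes (camera adjusted p = 0.0175; adjusted p = 0.513 with an estimated correlation).

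Of 12 inflammasome and pyroptosis genes 8 were higher and 0 lower, also when adjusted over the list alone, led by the cytokine Il1b (2.08 ± 0.33) and including the pore-forming Gsdmd (1.78 ± 0.37). The count was 4 after median-ratio scaling and 5 without sham 3 or ligated 2. The list median was 0.56 above all genes, and the camera call (adjusted p = 0.0278; adjusted p = 0.513 with an estimated correlation) was lost without sham 4 (0.0559) or ligated 1 (0.0753), without the 4 libraries with lymph node transcripts (0.0842) and with libraries rescaled to the same sum (0.0505). Apoptosis and necroptosis genes were higher in 16 of 22 and lower in 0, also when adjusted over the list alone, and 6 after median-ratio scaling. The necroptosis kinase gene Ripk3 (2.10 ± 0.46) rose. Their list median was 0.68 above all genes (camera adjusted p = 0.00643; adjusted p = 0.563 with an estimated correlation). Of 16 ferroptosis and iron genes 9 were higher and 0 lower, also when adjusted over the list alone, but after median-ratio scaling 2 were higher and 2 lower. Heme oxygenase Hmox1 (2.19 ± 0.34) and the iron reductase Steap3 (1.91 ± 0.21) led them. The list's median was 0.55 above all genes and camera did not pass (adjusted p = 0.486), but did with no filter (0.00735).

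Cell cycle genes were called higher in 6 of 25, lower in 0, and in 0 when adjusted over the list alone. The replication helicase gene Mcm6 rose by 1.69 ± 0.46 and stood at 13.0 FPKM in sham 1. The mean log2(FPKM + 1) of the list was highest in the libraries with lymph node transcripts, at 2.92 in sham 1 and 2.45, 2.66 and 3.04 in ligated 1 to 3, against 1.51 and 2.09 in ligated 4 and 5 and at most 0.99 in sham 2 to 5. With the lymph node and parotid levels as covariates 1 of 25 was higher, and Mcm3, Cdc20 and Ube2c were no longer called (0.80, 0.76 and 0.68). The count was 12 without sham 1 and 15 without ligated 4, but 2 without sham 2, 3, 4 or 5 or ligated 2 or 3, 3 without ligated 1, and 0 after median-ratio scaling. The median of the list was 0.59 above all genes. Camera did not pass (adjusted p = 0.777). It passed, higher, without sham 1 (0.0116), after median-ratio scaling (0.00708) and with quantile normalization (0.0117). It also passed, higher, without the 4 libraries with lymph node transcripts (0.0406) and without the 4 with parotid transcripts (0.0061). In fatty acid oxidation 4 of 20 genes were higher and 0 lower, also when adjusted over the list alone, led by Acaa2 (1.32 ± 0.30). The count was 1 without sham 3 or ligated 4, 2 without ligated 3 and 0 after median-ratio scaling. The median of its members was 0.07 above all genes (camera adjusted p = 0.951). Among ligated libraries the mean log2(FPKM + 1) of this list was highest in ligated 4 and 3 (4.26 and 4.08) and lowest in ligated 2 (3.37). The adipocyte list had the same ends (5.72, 5.33 and 3.23), with ligated 1 and 5 in the other order. Whether fat cells account for the rise was not tested.

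In glycolysis and hypoxia 4 of 20 genes were higher, led by the glycolytic regulator Pfkfb3 (2.40 ± 0.35), and 1 lower, the growth factor Vegfa (-1.12 ± 0.44), also when adjusted over the list alone. After median-ratio scaling 1 was higher and 1 lower. The call of Vegfa was lost without sham 2, 3, 4 or 5 or ligated 2, 3 or 5 (adjusted p 0.0710 to 0.105), with no filter (0.0961) and with the replicate block (0.0629). The change of Vegfa was -0.57 (adjusted p = 0.195) with libraries rescaled to the same sum and -0.20 (adjusted p = 0.54) without the 4 libraries with parotid transcripts. The list median was 0.14 above all genes (camera adjusted p = 0.576). Oxidative phosphorylation genes were called by limma in 0 of 39 in either direction, also when adjusted over the list alone and with voom. At an unadjusted p under 0.05, 10 were higher and 0 lower. The list's median was -0.27 relative to all genes. Its camera call, lower (adjusted p = 0.0485; adjusted p = 0.878 with an estimated correlation), was lost without sham 2 (0.0656), 4 (0.113) or 5 (0.118) and without ligated 2 (0.847) or 5 (0.0717), without the 4 libraries with parotid transcripts (0.874) or the 4 with lymph node transcripts (0.122), with the covariates (0.559), rescaled to the same sum (0.97), with the replicate block (0.107) and with a filter at 5 FPKM (0.0748), and turned higher without passing when no filter was used (0.748).

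Endothelial genes were higher in 14 of 17 and lower in 0, also when adjusted over the list alone, and 7 were higher after median-ratio scaling. Cdh5 (2.17 ± 0.28), the cadherin of vessel walls, and the adhesion molecule gene Selp (1.96 ± 0.29) rose. The median of the list was 0.96 above all genes (camera adjusted p = 0.00142; adjusted p = 0.513 with an estimated correlation). Of 15 regulators of gland development 6 were higher and 0 lower, also when adjusted over the list alone, and 5 after median-ratio scaling. Besides H19 these were led by the growth factor receptor Fgfr1 (1.85 ± 0.27), the transcription factor Sox4 (1.78 ± 0.23) and Ccn1 (1.74 ± 0.34). The median of its members was 0.18 above all genes (camera adjusted p = 0.451). Of 9 nerve and Schwann cell genes 0 were higher and 1 lower, also when adjusted over the list alone. It was the neurotrophin receptor Ngfr (-1.64 ± 0.51), and without ligated 1 or 3 another gene was called higher (1 of 9). Without the 4 libraries with parotid transcripts Ngfr was not called (-0.73, adjusted p = 0.0698). The list median was -0.13 relative to all genes (camera adjusted p = 0.714). Of 9 myoepithelial and smooth muscle genes only Des was called (3.24 ± 0.52), also when adjusted over the list alone, and 2 were higher without ligated 3. Des encodes desmin, which skeletal muscle also makes. The list's median was -0.38 relative to all genes. Its camera call, lower (adjusted p = 0.0446; adjusted p = 0.565 with an estimated correlation), was lost without sham 3 (0.058), 4 (0.113) or 5 (0.0644), without ligated 1 (0.0894) or 3 (0.318), after median-ratio scaling (0.164) and in 8 other settings (0.0507 to 0.594).

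Skeletal muscle and adipocyte transcripts were low in sham glands, and their mean level was higher in every ligated library than in any sham library. All 9 measured skeletal muscle genes were higher, also when adjusted over the list alone and after median-ratio scaling, with a median 3.55 above all genes. Acta1, the actin of skeletal muscle, went from 2.05 ± 0.679 to 196 ± 142 FPKM, and Atp2a1, its calcium pump, from 0.0250 ± 0.0234 to 35.2 ± 27.4 FPKM. Camera gave an adjusted p of 0.000606 (adjusted p = 0.513 with an estimated correlation), a call that was also lost with voom on recovered reads (0.125). All 9 measured adipocyte genes were higher, also when adjusted over the list alone and after median-ratio scaling, with a median 3.54 above all genes. Cfd, which encodes adipsin, went from 3.43 ± 4.86 to 293 ± 183 FPKM (adjusted p = 0.000117; ENSMUSG00000061780.6, chromosome 10 at 79890853 to 79892655), and the hormone gene Adipoq from 0.254 ± 0.286 to 42.4 ± 17.2 FPKM. Camera gave an adjusted p of 1.15e-06 (adjusted p = 0.409 with an estimated correlation). Without any 1 ligated library, fewer of these genes passed the filter, and 2 of 2 and 5 of 5 were higher.

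Of 5 measured parotid and sublingual gland products 0 were higher and 1 lower, also when adjusted over the list alone. The lower gene was Smgc (-2.33 ± 0.52), a mucin-like product that overlaps Muc19. The other members had positive but widely spread changes: Amy1 (3.72 ± 2.36), Smr3a (3.98 ± 2.82), Dnase1 (2.64 ± 1.72) and Bpifa2 (0.37 ± 2.56). The list median lay 2.12 above all genes, while camera, which compares t-statistics, placed the list lower than other genes (adjusted p = 0.035; adjusted p = 0.513 with an estimated correlation). That call was lost without sham 1 (0.128), where 2 genes were higher, and without ligated 1 (0.162) or 4 (0.243). It was also lost after median-ratio scaling (0.979), with no filter (0.205), with a filter at 5 FPKM (0.421) and without the 4 libraries with lymph node transcripts (0.0697). It turned higher without passing under quantile normalization (0.744). Mean log2(FPKM + 1) of 6 parotid genes was 9.05 in sham 1 and 9.37, 10.93 and 9.66 in ligated 2, 3 and 5, and at most 3.67 in the other 6 libraries. The list took 0.872% ± 1.75 of the summed FPKM in sham and 5.31% ± 5.46 in ligated glands (exact permutation test, two-sided, p = 0.167).

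Immediate early and heat shock genes were higher in 7 of 15 and lower in 0 (8 higher when adjusted over the list alone), and 2 after median-ratio scaling. The chaperone gene Hspb1 (1.94 ± 0.27) and the transcription factor Junb (1.78 ± 0.19) led them. The median of the list was 0.51 above all genes. Its camera call (adjusted p = 0.0493, and 0.513 with an estimated correlation) was lost without sham 1 (0.164), 4 (0.109) or 5 (0.0608) and without ligated 3 (0.116). It was also lost with voom on recovered reads (0.0525), rescaled to the same sum (0.112), with a filter at 5 FPKM (0.0629) and with a pseudocount of 0.1 (0.0625). The same held without the 4 libraries with parotid transcripts (0.164) and without the 4 with lymph node transcripts (0.0931). Erythroid genes were called by limma in 0 of 5 in either direction, also when adjusted over the list alone, with voom and at an unadjusted p under 0.05 (0 higher, 0 lower). Their median was -0.76 relative to all genes (camera adjusted p = 0.00344, lower; adjusted p = 0.513 with an estimated correlation), a call lost after median-ratio scaling (0.129), with quantile normalization (0.167) and without the 4 libraries with parotid transcripts (0.377).

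Of 13 mitochondrially encoded transcripts 1 was higher, mt-Nd3 (1.05 ± 0.39), and 0 when adjusted over the list alone. The call was lost without sham 3 (0.65) and without sham 5 or ligated 1, 4 or 5 (adjusted p 0.0530 to 0.0759). The median of its members was -0.15 relative to all genes (camera adjusted p = 0.451). Of 30 cytosolic ribosomal protein genes limma called 0 in either direction, also when adjusted over the list alone and with voom, and 29 were higher and 0 lower at an unadjusted p under 0.05. Without sham 1 the count of higher genes was 6 (camera adjusted p = 0.00805), without ligated 4 it was 1 (0.0458), and without ligated 5 it was 1. With libraries rescaled to the same sum all 30 were higher. Their median was 0.13 above all genes (camera adjusted p = 0.248).

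**Figure D4:**
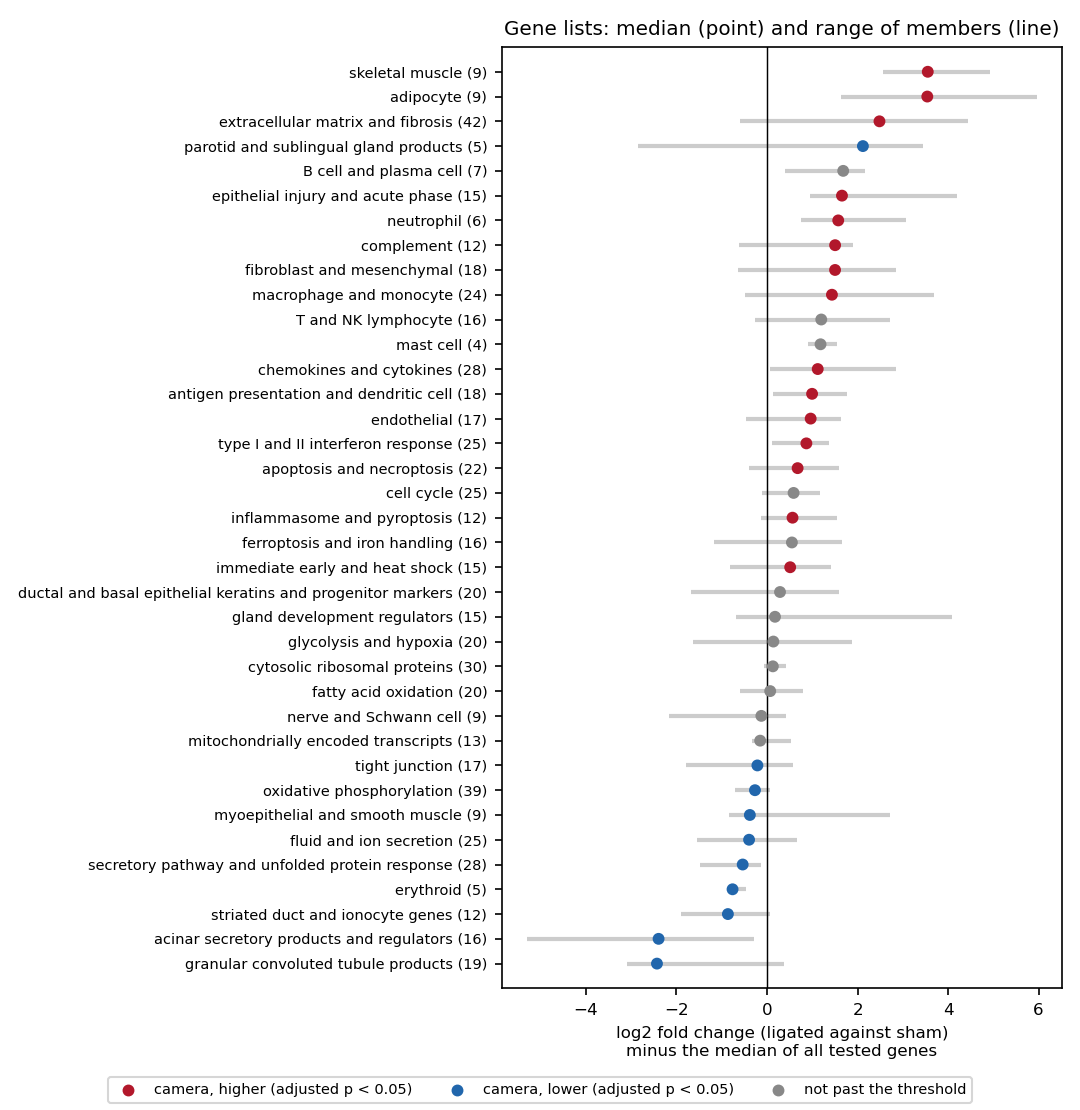
Median log2 fold change of each gene list minus the median of all genes (points), with the range of its members (lines), coloured by camera with the preset correlation (red higher, blue lower, grey not past the threshold). Skeletal muscle, adipocyte and extracellular matrix lists lie farthest right (3.55, 3.54 and 2.48), and granular convoluted tubule and acinar lists farthest left (-2.43 and -2.40).

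As shares of the summed FPKM, 27 of 38 lists were higher in ligated glands and 1, the acinar list, was lower (exact permutation test, two-sided, adjusted over the 38 lists). The smallest p possible, 0.00794, was reached by most of them and corresponds to an adjusted p of 0.0126. Macrophage genes took 0.0809% ± 0.0507 in sham and 0.636% ± 0.207 in ligated glands, injury and acute phase genes 0.0352% ± 0.0242 and 0.489% ± 0.221, adipocyte genes 0.00181% ± 0.00152 and 0.162% ± 0.105, and mitochondrially encoded transcripts 2.28% ± 0.494 and 4.48% ± 1.41 (each adjusted p = 0.0126 in the exact test). Without the 20 highest genes, 16 lists were higher and 3 lower. The granular convoluted tubule list was then lower by exact test (adjusted p = 0.0335), and differences in mitochondrially encoded (-0.255), oxidative phosphorylation (-0.205), secretory pathway (-0.519) and tight junction genes (-0.0259) turned negative without passing. The neutrophil share (adjusted p = 0.0348 in the exact test) did not pass without sham 2, 3, 4 or 5 (0.0624 to 0.0696).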

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

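In this part, the 9 tests of explanations were chosen only after the result had been seen, whereas the 4 counts over other splits of the libraries were planned.

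Values were looked at again when 1 of the 5 libraries of a group stood far from the other 4 (Dixon's criterion at 95%). Of 330 groups of values, 62 held such a library, where chance gives about 1 in 20. In sham 1 these were 38 genes and 14 lists, and in ligated 1 they were 4 genes. The values are of named genes and lists that share members, so they are not independent.

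Sham 1 stood above the other shams in the mean log2(FPKM + 1) of lists for B and plasma cells (5.97), parotid and sublingual products (4.97), antigen presentation (4.58), lymph node (4.10), cell cycle (2.92), T and NK cells (2.82), apoptosis (2.67), endothelium (2.66), interferon response (2.51), chemokines (2.13), injury (1.94), inflammasome (1.73) and neutrophils (1.38). It stood below them for granular convoluted tubule products (10.805).

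Sham 1 also held the highest sham FPKM of lymphoid and antigen-presenting genes, with Cd74 at 1216, Ccl21a at 233.9, H2-Eb1 at 231.9, H2-Ab1 at 211.9, Trbc2 at 60.9, Cd8b1 at 16.3, Cd8a at 10.7, Il7r at 6.88 and Itgax at 3.73. Of myeloid and mast cell genes it had Lyz2 at 394.3, Ctss at 101.1, S100a9 at 21.2, S100a8 at 8.80, Mefv at 1.05 and Cpa3 at 1.94. Of inflammatory and cell death genes it had Il33 at 26.8, Bcl2a1d at 11.1, Gsdmd at 6.05, Ripk3 at 5.06 and Il18 at 4.20, and of cell cycle genes Mcm6 at 13.0, Mcm3 at 12.4, Cdc20 at 11.3 and Ube2c at 8.03. Vessel genes were Pecam1 at 17.0, Icam1 at 11.4 and Cdh5 at 10.1. The rest were Clu at 122.4, Vim at 70.4, Atp1b3 at 44.0, Junb at 35.4, Des at 8.16, Pfkfb3 at 4.85, Mylpf at 1.67, Cidec at 1.58, Orm1 at 1.20 and Tnnt3 at 0.0977, and Klk1b4 was the lowest sham value at 4403.

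Sham 3 had more assigned reads than the other sham libraries, at 17305592. Sham 2 had the highest sham value of H19, at 8.37 FPKM. Ligated 1 was the lowest ligated library for Timp1 (39.2 FPKM), Clu (128.4), C5ar1 (7.25) and Fth1 (259.6). Ligated 4 was lowest for the acinar list (4.79) and for Dcpp2, listed at 0 FPKM, and highest for the glycolysis and hypoxia list (4.86). Ligated 2 was highest for the interferon list (3.86).

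Lymphoid and parotid transcripts were high in sham 1 and in some ligated libraries. For parotid genes a response to ligation was argued against, since 2 ligated libraries lay at or below the maximum of sham 2 to 5. For lymph node genes neither bound was met. A response would place all ligated libraries above all sham libraries, and sham 1 (4.10) lay above every ligated library. Against a response, 0 ligated libraries lay at or below the maximum of sham 2 to 5 (0.596), with 0.790 in ligated 4 and 0.662 in ligated 5. These 2 lay close to it and far below ligated 1 to 3 (3.51, 3.58 and 3.92). A response of lymph node genes stays open in the ligated libraries. A wrong label on sham 1 was argued against by its extracellular matrix level, 1.72 below the lowest ligated library on the log2 scale. Lymph node or parotid tissue taken along at dissection stays open as a candidate source, and it was not tested on genes other than those that pointed to it. The most abundant of these transcripts in sham 1 were Bpifa2 at 14814 and Amy1 at 3358 FPKM.

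Y-linked transcripts were present in all 10 libraries labelled female, with a lowest value of 0.770 FPKM among 4 genes, and Xist reached at most 0.0267 FPKM. Reads of X-linked homologs placed on the Y-linked genes were argued against, since 2 of 4 homolog pairs had a ratio over 0.1 in every library. Loss of Xist reads to the antisense gene Tsix was argued against, since Tsix exons cover 11.03% of Xist exon bases. Male RNA in the libraries is what these values fit, and a sex label that differs from the animals used is a candidate explanation. No biological explanation was tested, as the design names a single sex.

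Adipocyte and skeletal muscle transcripts were higher in all ligated libraries. A rise of every other FPKM through the loss of secretory transcripts was argued against, since their median log2 fold change after median-ratio scaling was 3.72 (SE 0.25, 18 genes). A lower share of gland epithelium alone would raise all other cell types alike. The lower median of these 2 lists lay 2.04 (SE 0.53, over genes and not mice) above the fibroblast list, the highest of 4 lists of other cell types. Genes near 0 in sham glands pass the filter only through their ligated values, which favours large medians in these 2 lists. Over all list members, unfiltered, the mean log2 level of adipocyte genes was 0.27 to 1.10 in sham and 3.23 to 5.72 in ligated libraries. For skeletal muscle genes it was 0.14 to 0.30 and 1.56 to 4.80, and for fibroblast genes 1.86 to 2.20 and 3.21 to 4.25. These levels argue against a lower share of epithelium alone. Of 15 further muscle genes, 11 had every ligated value above every sham value, between the bounds set for and against muscle from around the gland. Groups did not overlap, in either direction, in 31.3% of all tested genes. The count shows more muscle transcripts in ligated libraries and cannot tell their source, since muscle from any source would raise it. Skeletal muscle from around the gland therefore stays open. That count bears on muscle only, and where the fat came from was not tested. A response of the gland itself to ligation was not tested and stays open too.

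Among 100 splits of the 10 libraries, with the real split among them, 1 gave at least 2031 genes higher, the real split itself (highest other 1692). For genes lower, 2 splits gave at least 138, the real split and another with 148. Both results lie under the bound of 1 in 20 set beforehand. This makes chance unlikely for both counts but does not exclude it, as 100 of 126 possible splits were drawn. At least 15 lists higher were given by 17 splits (highest other 20) and at least 10 lower by 22 (highest other 18), the real split again counted, so chance cannot be excluded for the counts of lists. The other split with the most genes set sham 1 and ligated 2 to 5 against the rest. It differs from the real split only by the exchange of sham 1 and ligated 1, so its count does not show a further structure of the samples.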

How the results depend on the processing

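The lymph node and parotid covariates, the fits without the 4 libraries with lymph node or with parotid transcripts, and voom were chosen after seeing the data, and all other settings were planned; where a value moved, the cause was not tested unless stated. Genes higher (2031) and lower (138) were 1166 and 101 with a filter at 5 FPKM (fewer genes tested), 811 and 498 with median-ratio scaling, 6675 and 78 rescaled to the same sum, 689 and 509 with quantile normalization, 1697 and 84 without the parotid libraries, 3153 and 193 with voom, and 6732 and 397 with no fold threshold. Leaving out 1 library gave 1606 to 2618 higher and 99 to 200 lower. Lists higher (15) were 0 with an estimated correlation and 24 with fry, and 11 to 16 with 1 library left out. Lists lower (10) were 5 with no filter, 6 at 5 FPKM, 6 with median-ratio scaling, 5 with quantile normalization, 6 with covariates, 5 without the lymph node libraries, 1 with an estimated correlation and 1 with fry, and 7 to 9 with 1 library left out. The gap between groups on the first component (9.26% of the range) was -15.5 with median-ratio scaling, -16.8 with quantile normalization, 78.2 without the lymph node libraries, 65.5 without the parotid libraries, and 1.57 to 56.1 with 1 library left out. Without the 20 highest genes, 16 lists had a higher share of the summed FPKM and 3 a lower one, and with 1 library left out 24 to 29 and 1 to 1. Log2 fold changes of 4 genes that were not called changed sign. Cox6a1 was -0.45 with median-ratio scaling and -0.39 with quantile normalization, and Rplp1 -0.13 with median-ratio scaling. Hspa5 was 0.43 rescaled to the same sum, 0.0021 without ligated 2 and 0.21 without the parotid libraries, and -0.26 to 0.0021 with 1 library left out. Hbb-bs was 0.32 rescaled to the same sum, 0.0048 without ligated 2, 0.0058 without ligated 5 and 0.63 without the parotid libraries, and -0.62 to 0.0058 with 1 library left out. Oxidative phosphorylation turned higher with no filter (adjusted p = 0.748) and parotid and sublingual products with quantile normalization (adjusted p = 0.744). With fry, which does not compare a list with other genes, 7 lists that passed in camera or in fry turned higher, with adjusted p of 0.278 for fluid and ion secretion, 0.0363 for keratins, 0.352 for myoepithelial, 0.149 for oxidative phosphorylation, 0.278 for tight junction, 0.00346 for nerve and 0.878 for parotid products. The B and plasma cell (fry adjusted p = 0.0971) and mitochondrially encoded lists (0.130) turned higher too and passed in neither. Among shares that had passed, the differences that turned negative without the 20 highest genes were -0.519 for the secretory pathway, -0.205 for oxidative phosphorylation, -0.0259 for tight junction and -0.255 for mitochondrially encoded transcripts. Of the named genes, 95 had the same direction and side of the threshold with median-ratio scaling, 89 with quantile normalization, 111 with no filter, 124 with a pseudocount of 0.1, 122 with robust moderation and 123 with voom. With the replicate number as a block, 2082 genes were higher and 121 lower and 15 lists higher and 7 lower. Deviations of same-numbered libraries correlated at 0.178, -0.378, -0.0798, 0.329 and 0.577, so no steady pairing by number was seen. They were not compared with differently numbered libraries, and whether the numbers pair the samples is not known. At 12105738 to 17305592 reads, values near 3 reads (0.173 to 0.248 FPKM for 1 kilobase) rest on too few reads to show a change.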

Other observations

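Genes in this part were chosen after their values had been seen, and so were the tests that bear on them. Fasn, which encodes fatty acid synthase, went from 11.2 ± 3.77 to 120.2 ± 93.9 FPKM (mean ± SD, n = 5; log2 change 2.97 ± 0.51, SE, limma adjusted p = 0.00118), and the desaturase gene Scd1 rose by 3.05 ± 0.62. The last step of triglyceride synthesis, Dgat2, rose by 3.86 ± 0.49, the lipase gene Lpl by 3.31 ± 0.30, and the fatty acid carrier Cd36 by 3.36 ± 0.25. The adipocyte transcription factor Pparg rose by 2.39 ± 0.25 and Thrsp by 4.33 ± 0.53. Fasn was highest in ligated 3 and 4 (188.3 and 249 FPKM), the libraries with the highest mean log2 level of the adipocyte list (5.33 and 5.72). The calls of Fasn, Scd1, Lpl, Cd36 and Thrsp held in all 22 settings that tested them, Dgat2 in 20 of 20 and Pparg in 14 of 14.

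Pigr, which encodes the receptor that carries antibodies into saliva, fell by 1.31 ± 0.26, and Ccl28, a chemokine for antibody-secreting cells, fell by 2.24 ± 0.30, from 77.4 ± 25.7 to 15.97 ± 6.69 FPKM (adjusted p = 0.000329). The protease inhibitor gene Wfdc12 fell by 2.01 ± 0.35, the stress gene Nupr1 by 1.88 ± 0.37, the calcium pump gene Atp2a3 by 1.36 ± 0.29 and the receptor kinase gene Ret by 1.37 ± 0.29. The calls of Ccl28, Wfdc12 and Nupr1 held in 22 of 22 settings and those of Atp2a3 and Ret in 20 of 22. Pigr held in 21 of 22, and rescaled to the same sum its change was -0.76. None of the settings accounted for sublingual tissue. In sham glands Ccl28 and Smgc, listed here with sublingual products, had the same order of libraries, from sham 3 (53.0 and 2.17 FPKM) to sham 4 (115.5 and 18.1 FPKM). In ligated glands Ccl28 was lowest in ligated 2 (8.61 FPKM), where Smgc was highest (3.63 FPKM). Whether less sublingual tissue lowered Ccl28 was not tested.

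A hypothesis is that Fasn and the genes named with it rose together with the fat cells in the samples, and may say little about gland cells. The rise of adipocyte and skeletal muscle genes by a median of 3.72 after median-ratio scaling shows that such transcripts were present beyond any shift of scale. Whether Fasn and the genes named with it also rose in gland cells was not tested, nor was whether the fat lay in the gland or around it.

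A hypothesis is that Muc19, Dcpp2 and A2ml1 fell in part because the ligated samples held less sublingual tissue, since they followed Smgc, listed here with sublingual products. Whether Smgc came from sublingual tissue alone was not tested. A fall of Smgc in submandibular cells would give the same pattern. Muc19 overlaps Smgc, so its r may come from shared reads and is not independent support. Dcpp2 followed Smgc less closely in ligated glands (0.65) than A2ml1 did (0.92). Its copies Dcpp1 and Dcpp3 were not called, so the fall of Dcpp2 itself is uncertain. In sham glands 4 acinar genes had a negative r with Smgc, namely Pip (-0.43), Prol1 (-0.89), Lpo (-0.52) and Car6 (-0.02). Their median log2 change was -1.99 (SE 0.31, over genes and not mice). This argues against less sublingual tissue as the cause for the whole acinar list. The argument rests mainly on Prol1 and Pip, since Car6 was near 0 and Lpo had a positive r in ligated glands (0.50). The sign of each r rests on 5 libraries. For the genes that followed Smgc, less sublingual tissue stays open, beside a response of the gland to ligation.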
